A study of Mus musculus with 6 samples.

How the data were processed

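Gene expression was measured in single cells (10x Genomics 3′ v2 chemistry, per the labels' protocols) from subcutaneous tumours of 3 groups, LKR13K, LKR13KL and LKR13KL MCT4KO, with 2 samples each. The deposited values are whole UMI counts per gene and cell, although the file is named as normalized, and their cell totals are unequal as raw counts are. The submitters' processing notes name Cell Ranger, Seurat 3.1.5 and the mouse build mm10, without the steps or their order. Cell totals ran from 500 to 51490, every cell had at least 201 genes and at most 15.0% mitochondrial counts, so filters appear to have been applied before the counts were deposited. How malignant cells and doublets were removed is not given in the sources used here, and no cell type annotation by the authors was used here. The table held 9802 cells and 22497 genes, of which 2975 were 0 in every cell. Cells were assigned to samples by the suffix of their column names, and 0 columns were left unused.

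LKR13K replicate 2 had been counted with a different gene annotation from the other libraries. Therefore 150 pairs of symbols of the same gene were merged and 315 genes were left out, 84 at 0 in that library alone and 231 counted in it alone, which left 22032. Without this step 2 of 25 clusters, with 620 cells, came from that library alone, and with it 0 of 23 did. The step was chosen after the data were seen.

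Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1.0 were used without batch integration (Python 3.11.15, scanpy 1.11.5, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). A cluster took the name of the class with the most fixed markers among its 100 leading genes, needed 3, and stayed unnamed where its top 10 genes held more markers of another class. Names end in "-like" because they rest on transcripts alone. Scrublet marked 7 cells (0.071%) as doublets, too few for its call to be usable, so no cell was removed.

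Counts were summed per sample and class and tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, R 4.3.3), all 6 samples in 1 fit with the group as the only factor. This is the test written down for files that turn out to hold counts. Classes needed 20 cells in every sample, which 8 did, and genes 0.1 counts per 10000 in 2 samples. P-values were adjusted by Benjamini-Hochberg within class and comparison, at a threshold of 0.05. Gene lists were tested with camera of limma 3.58.1 (preset correlation, then an estimated one) and with fry. DESeq2 1.42.0 and limma with trend and a pseudocount of 0.1 per 10000 were run as alternatives. Class shares were compared by a two-sided exact permutation test. The groups, tests, lists, markers, thresholds and most alternatives were fixed before the data were examined.

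The genes named are those that passed with both samples of one group above both of the other, the 6 highest and 6 lowest by fold in T cell-like and macrophage-like cells and 3 and 3 elsewhere. Where fewer passed, the genes with the smallest p and the same separation are named and said not to pass. Up to 4 members of each list in the class it is about, members adjusted over the list alone, and Slc16a3 and Stk11 are named too. Mitochondrial, ribosomal, sex-linked and predicted genes and antigen receptor segments are counted but not named.

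Tested on simulated data with 200 changed genes, edgeR called from 13.4% to 94.0% of genes changed 4-fold over the classes. It called at most 15 unchanged genes in 1 class. That class, cluster 8, had 2, 28 and 51 calls of genes changed 2-, 4- and 8-fold. T cell-like cells had 12 unchanged genes called, beside 15, 56 and 64. In both, unchanged genes made up a larger share of the calls than the adjusted p threshold of 0.05. This also held in fibroblast-like (11 unchanged genes) and endothelial cell-like cells (6). It did not hold in macrophage-like cells and cluster 9 (4 each) or in monocyte-like and neutrophil-like cells (0 each). Replicates of a group were checked for being duplicates: the chi-square over degrees of freedom between them was 54.0, 44.9 and 44.4, far above the value of 1 that repeated sampling of the same library would give. Alternatives varied the test, scaling, filter, clustering resolution, doublet treatment, annotation step, cells used and each library in turn. Other analyses, such as trajectories, receptor clonotypes and cell communication, were not analysed here.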

Results

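Single cells were profiled from subcutaneous tumours grown in 129SV mice, an inbred mouse strain. The tumours came from 3 related lung adenocarcinoma cell lines. LKR13K carries mutant Kras, LKR13KL also lacks Stk11 (the LKB1 kinase), and LKR13KL MCT4KO further lacks Slc16a3, which encodes the lactate exporter MCT4. The deposited matrix is described as holding the non-malignant cells, so the cells measured are host cells and not the edited tumour cells. Each group had 2 samples, and 9802 cells were deposited in total. LKR13K replicates 1 and 2 held 1767 and 1323 cells with 11775887 and 6979241 counted transcripts (UMIs). LKR13KL replicates 1 and 2 held 3759 and 812 cells with 22437330 and 6042680 UMIs, and LKR13KL MCT4KO replicates 1 and 2 held 1463 and 678 cells with 10520810 and 4459681 UMIs. The labels do not say whether replicates came from separate mice. Every p-value of a single gene or share therefore measures only the spread between these samples, which may be technical. Camera p-values instead compare the genes of a list with the other genes tested. With the preset correlation they also rest on that assumed value. Values below are mean ± SD of 2 samples unless stated otherwise, and fold changes are log2 ± standard error. For edgeR this standard error is the size of the log2 fold change divided by the square root of the F statistic. It was not estimated by the fit itself.

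Clustering separated T cell-like cells, NK cell-like cells, B cell-like and plasma cell-like cells, macrophage-like, monocyte-like, neutrophil-like, dendritic cell-like and mast cell-like cells, and fibroblast-like, pericyte-like and endothelial cell-like cells. The T cell-like class joined a Cd4 and Tcf7 cluster (cluster 0), a Cd8a, Prf1 and Pdcd1 cluster (cluster 4), a Foxp3, Il2ra and Ctla4 cluster (cluster 10) and a small Trdc cluster (cluster 21). The macrophage-like class joined an Arg1 cluster (cluster 2) and a cluster led by the stress genes Hspa1a and Fos with Ly6i and Lyz2 (cluster 7). Another 5 clusters with 2142 cells stayed unnamed by the fixed marker rule and are given by number. Clusters 8 and 9 held 11 and 8 macrophage markers among their 100 leading genes. Their top 10 genes each held 0 of these and 1 marker of another class, so they are outside the macrophage-like class. Cluster 3 was led by Areg, Nos2 and Il6, cluster 8 by Cbr2, Cd163 and Folr2, cluster 9 by Ccl24, Mmp12 and Mgl2, cluster 14 by the interferon-response genes Cmpk2, Rsad2 and Ifit1, and cluster 16 by Tagln and Acta2. Lyz2, a myeloid lysozyme gene, was detected in 89.2%, 97.2%, 93.9% and 85.7% of the cells of clusters 3, 8, 9 and 14.

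Slc16a3 and Stk11, the genes altered in the tumour lines, were read in every sample first. Over all cells, Slc16a3 reached 66.1 and 74.6 counts scaled to the library total (CPM) in the LKR13K samples, 141 and 125 in the LKR13KL samples and 161 and 138 in the LKR13KL MCT4KO samples. Stk11 reached 61.0 and 70.3, 53.7 and 60.1, and 44.1 and 51.2 CPM in the same order. Neither gene passed the edgeR test in any of the 8 classes tested, with smallest adjusted p of 0.587 for Slc16a3 and 0.705 for Stk11 over the 3 comparisons. Because the host cells were not edited, these levels check little about the labels. Slc16a3 lies on chromosome 11 from 120948480 to 120960868 and Stk11 on chromosome 10 from 80115803 to 80130682 (GRCm38), and the counts are gene totals that do not separate exons.

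The first comparison, LKR13KL against LKR13K, asks how loss of Stk11 in the tumour line accompanies differences in the surrounding host cells. T cell-like cells made up 14.9% ± 13.1 of LKR13KL cells and 34.1% ± 5.30 of LKR13K cells. Plasma cell-like cells made up 0.266% ± 0.376 against 2.57% ± 1.49, dendritic cell-like cells 1.37% ± 0.888 against 3.77% ± 0.125, and mast cell-like cells 0.0798% ± 0.113 against 0.953% ± 0.493. Macrophage-like cells stood at 17.5% ± 0.713 in LKR13KL and 10.2% ± 5.23 in LKR13K, and fibroblast-like cells at 15.4% ± 8.55 and 5.97% ± 2.36. The macrophage-like difference turned to −0.235 percentage points with clustering at resolution 2.0. It also leaves out clusters 8 and 9, which held macrophage markers. Cluster 8 made up 8.21% and 8.47% of cells in LKR13K replicates 1 and 2 and 3.27% and 6.40% in LKR13KL. Cluster 9 made up 1.75% and 8.995% against 1.04% and 17.98%. Both LKR13KL samples lay on one side of both LKR13K samples for 9 of 17 classes and clusters, with 4 higher and 5 lower, where chance gives 33.3%. No share difference could pass the two-sided exact permutation test, whose smallest p with 2 against 2 samples is 0.333, and the smallest adjusted p was 0.63. No plasma cell-like or mast cell-like cell was found among the 812 cells of LKR13KL replicate 2, which allows a share of up to 0.369%. The median UMI count of macrophage-like cells was 1045 and 1054.5 in the LKR13K samples and 3053.5 and 2396 in the LKR13KL samples, a depth gap that can move cells between classes.

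**Figure D1:**
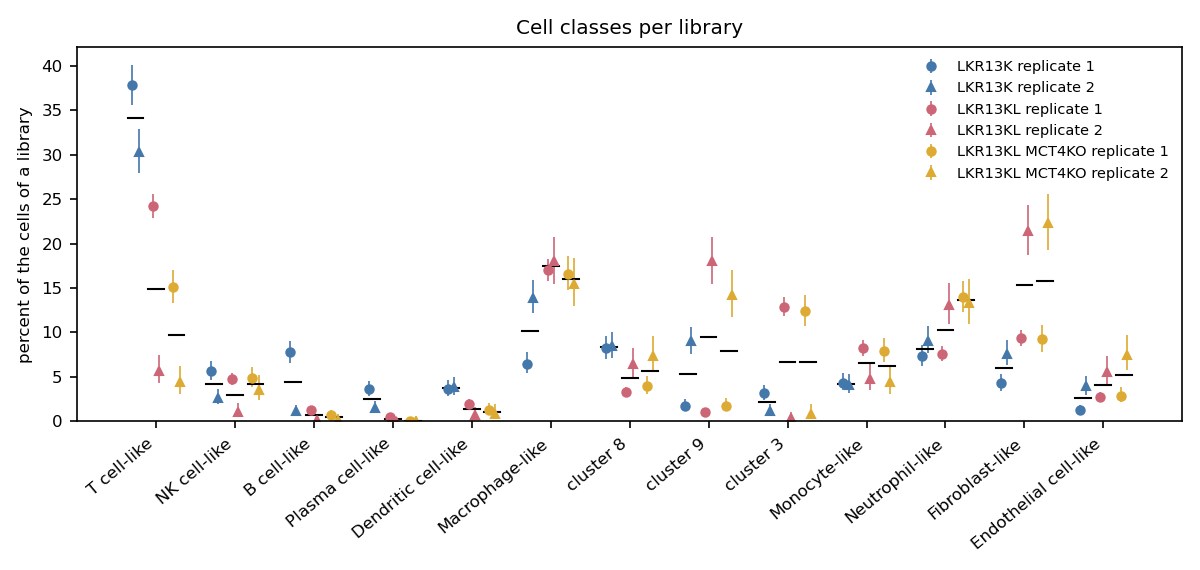
Percent of the cells of each library (y axis) in 13 cell classes and clusters (x axis), one point per library with its Wilson 95% interval, which covers counting error only; black bars are group means. T cell-like shares were 37.8% and 30.3% in LKR13K, 24.2% and 5.67% in LKR13KL, and 15.1% and 4.43% in LKR13KL MCT4KO.

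In T cell-like cells of LKR13KL tumours Itgae, Cdh1, Xcl1 and Glp1r were among the genes called lower. Itgae, the CD103 integrin chain that binds E-cadherin, stood at 11.5 ± 5.24 CPM in LKR13KL and 67.0 ± 22.7 CPM in LKR13K, a log2 fold change of −3.003 ± 0.43 (edgeR adjusted p = 0.0162). Cdh1, which encodes E-cadherin itself, fell with a log2 fold change of −4.72 ± 0.66, from 23.3 ± 7.06 to 0.443 ± 0.627 CPM (adjusted p = 0.0162, edgeR). Xcl1, a chemokine for cross-presenting dendritic cells, fell by 3.15 on the log2 scale, from 35.1 ± 1.05 to 2.11 ± 2.98 CPM (edgeR adjusted p = 0.0162). Glp1r, the receptor for glucagon-like peptide, changed most among the named genes, from 34.7 ± 12.4 to 0.332 ± 0.470 CPM (log2 fold change −5.62 ± 0.66, edgeR adjusted p = 0.0042). Abcb1a, an efflux pump, and Klra5, a receptor of the Ly49 family, fell by 1.86 and 2.46 on the log2 scale (edgeR adjusted p = 0.0455 and 0.0479). Klra5 has close copies in its family, so its count is uncertain. Cenpf, a kinetochore protein of dividing cells, rose from 25.3 ± 11.2 to 94.96 ± 27.1 CPM (log2 fold change 2.06 ± 0.35, edgeR adjusted p = 0.0476). The LKR13KL replicate 2 value of Cenpf rests on 15 counts, of which 13 lay in 1 cell.

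In this class edgeR called 13 of 7851 genes, 2 higher and 11 lower in LKR13KL, with 617 at an unadjusted p under 0.05. Limma with a pseudocount of 0.1 called 0 genes in this class, and edgeR called 0 with the gene symbols left as deposited. The lower genes not named above were 4 T cell receptor segments and a predicted gene. Gzmf, a granzyme, was called higher (log2 fold change 3.74 ± 0.64, edgeR adjusted p = 0.0476), but it was read in LKR13KL replicate 1 alone of that group. Replicate 1 held 910 of 956 LKR13KL T cell-like cells, and without it 2 genes were called. The log2 fold changes without it were −2.16 for Itgae (adjusted p = 0.489), −8.66 for Glp1r (0.412), −8.15 for Cdh1 (0.46) and −8.71 for Xcl1 (0.318). The last 3, like Gzmf, had a count of 0 in replicate 2, which with 46 cells allows up to 15.9 CPM. Gzmf stood at 2.60 and 2.29 CPM in the LKR13K samples, below that limit, and Glp1r, Cdh1 and Xcl1 above it. Without LKR13K replicate 1 Itgae had −2.54 (adjusted p = 0.0866), Cdh1 −4.33 (0.167) and Xcl1 −3.14 (0.0666), and without LKR13K replicate 2 Xcl1 had −3.205 (0.111). Abcb1a and Klra5 were called in 1 of 6 fits without 1 library. Without LKR13KL replicate 1 they had −1.93 (adjusted p = 0.435) and −1.59 (0.564), without LKR13K replicate 1 −1.97 (0.0931) and −2.15 (0.345), and without LKR13K replicate 2 −1.77 (0.379) and −2.599 (0.226). Without LKR13KL MCT4KO replicates 1 and 2 Abcb1a had an adjusted p of 0.0747 and 0.0783, Klra5 0.0646 and 0.0718, Cenpf 0.0963 and 0.084 and Gzmf 0.0964 and 0.101. Cenpf was called in 2 of 6 fits, with 1.65 without LKR13KL replicate 1 (0.466) and 1.597 without LKR13K replicate 1 (0.27). Gzmf was called in 1 of 6, with 3.78 without LKR13K replicate 1 (0.183) and 3.59 without LKR13K replicate 2 (0.335). Without LKR13KL replicate 2 edgeR called 44 genes, without LKR13K replicate 1 it called 27, and without LKR13KL MCT4KO replicate 2 it called 8. Cluster 4 made up 34.6% and 52.4% of T cell-like cells in LKR13K replicates 1 and 2 and 29.5% and 10.9% in LKR13KL, and cluster 10 made up 19.9% and 19.5% against 13.2% and 47.8%. Within cluster 4, Itgae still stood at 44.3 and 36.5 CPM in LKR13K and at 2.41 CPM in LKR13KL replicate 1, and Cdh1 at 47.1 and 22.2 CPM against 1.21 CPM. Krt8 and Krt18, keratins of epithelial cells that free RNA or tumour cells would bring, stood at 25.1 ± 7.35 and 25.7 ± 0.612 CPM in LKR13KL and at 31.98 ± 12.2 and 40.1 ± 14.5 CPM in LKR13K and did not pass. Sprr1a, a cornified envelope gene of epithelial cells, stood at 15.05 and 28.03 CPM in the LKR13K samples and at 1.99 and 0 in the LKR13KL samples (log2 fold change −3.44 ± 0.66, edgeR adjusted p = 0.0684). Itgae lies on chromosome 11 from 73090583 to 73147446, Cdh1 on chromosome 8 from 106603351 to 106670246, Glp1r on chromosome 17 from 30901817 to 30940791 and Xcl1 on chromosome 1 from 164931644 to 164935527 (GRCm38).

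**Figure D2:**
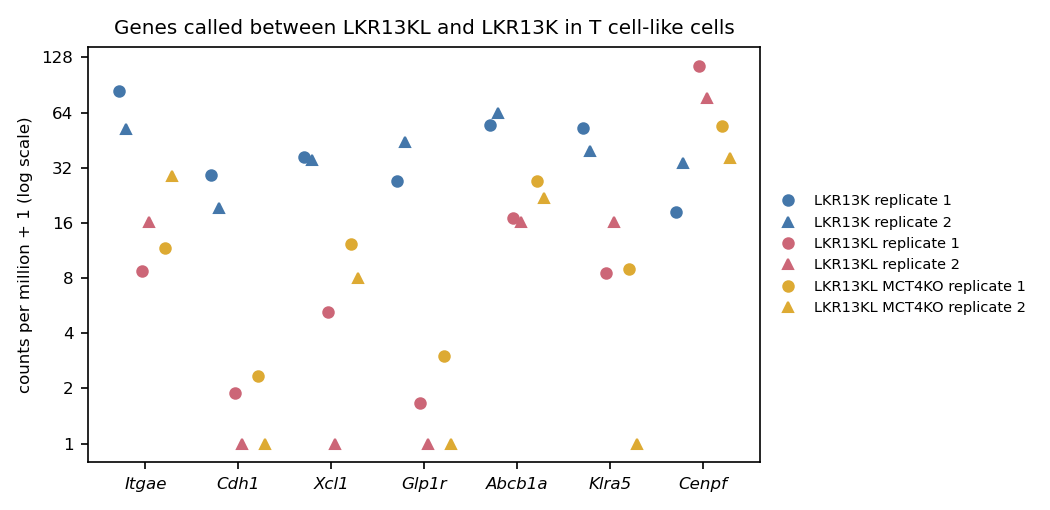
CPM plus 1 on a log axis (y) of 7 genes called between LKR13KL and LKR13K (x) in T cell-like cells, one point per library, with shapes for replicates. Both LKR13K points lie above both LKR13KL points for 6 genes and below them for Cenpf, whose means were 25.3 and 94.96.

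Of the gene lists fixed beforehand, the exhaustion and checkpoint list was lower in LKR13KL T cell-like cells. Of its 16 measured members 11 were lower and 5 higher, and camera gave an adjusted p of 7.16e-05. That call was lost with an estimated correlation (adjusted p = 0.882 with an estimated correlation) and without LKR13KL replicate 1 (0.639). Adjusted over the list alone, 9 members fell: Pdcd1 (PD-1), Lag3, Cd200, Cd38, Cd244, Tox, Eomes, Nr4a2 and Nr4a3. Over all genes tested none of these passed. Tox, a transcription factor of exhausted T cells, had 26.3 ± 12.8 CPM in LKR13KL and 57.9 ± 10.6 in LKR13K, and Lag3, an inhibitory receptor, had 103 ± 33.3 against 213 ± 72.4. Cell cycle genes were higher, 19 of 20 members (camera adjusted p = 3.13e-10), and adjusted over the list alone 9 rose, among them Cenpf, Mki67, Top2a and Ccnb2. The adjusted p was 0.882 with an estimated correlation, and 0.536 without LKR13KL replicate 1. Glycolysis and lactate transport genes were higher in 17 of 22 members (camera adjusted p = 0.0296, and adjusted p = 0.882 with an estimated correlation), and Slc2a3, a glucose transporter, rose adjusted over the list alone. That list was not called without LKR13K replicate 2 (0.343), LKR13KL replicate 1 (0.17) or LKR13KL replicate 2 (0.0578). The cytotoxic effector list split, with 9 members higher and 11 lower (camera adjusted p = 0.752). Adjusted over the list alone Gzmc, Gzmf and Ifng rose, and Fasl, Klrc1 and Ccl5 fell. Regulatory T cell genes had 4 members higher and 9 lower (camera adjusted p = 0.752), with Itgae lower adjusted over the list alone, and naive and memory T cell genes had 2 higher and 8 lower (camera adjusted p = 0.752). No list in any class was called by fry or by camera with an estimated correlation, in any of the 3 comparisons.

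Macrophage-like cells showed no gene past the edgeR threshold, with 262 of 7117 genes at an unadjusted p under 0.05, 7 called by DESeq2 and 0 by limma with a pseudocount of 0.1. Without LKR13K replicate 1 edgeR called 4. The genes with the smallest p included Ccl17, a chemokine for T cells that express Ccr4, with 38.5 ± 6.06 CPM in LKR13KL and 235 ± 86.5 in LKR13K (adjusted p = 0.728), and Ly6a, an interferon-inducible surface antigen, with 845 ± 405 against 222 ± 130. Neither passed. MHC class I presentation genes were higher in 14 of 15 members, interferon gamma response genes in 14 of 16 and hypoxia response genes in 16 of 17 (camera adjusted p = 0.01, 0.01 and 0.0103). All 3 had an adjusted p = 0.948 with an estimated correlation. None of the 3 was called without LKR13KL replicate 1 (0.526, 0.707 and 0.315), the first 2 were lost without LKR13K replicate 2 (0.174 and 0.294), and the hypoxia list without LKR13K replicate 1 (0.149). Alternative (M2-type) genes split into 8 higher and 9 lower and classical (M1-type) genes into 10 and 5 (camera adjusted p = 0.416 and 0.912). Cluster 2 made up 78.3% and 73.4% of macrophage-like cells in LKR13K and 45.8% and 58.2% in LKR13KL, and the stress-gene cluster 7 the remainder. The dissociation stress list had 9 members higher and 11 lower (camera adjusted p = 0.416).

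In cluster 8, the unnamed Cd163 and Folr2 cluster, the MHC class II list was lower in LKR13KL. All 11 members were lower (camera adjusted p = 2.54e-09, and adjusted p = 0.372 with an estimated correlation), and H2-Aa, H2-Ab1, H2-Eb1, Cd74, Ciita, H2-Oa and H2-DMb2 fell adjusted over the list alone. H2-Aa had a log2 fold change of −1.63 ± 0.50 and Ciita, the master regulator of these genes, −2.38 ± 0.74, and neither passed over all genes. MHC class I presentation genes split into 8 higher and 7 lower (camera adjusted p = 0.912). Hypoxia response genes were lower in 12 of 15 members (camera adjusted p = 0.000107, and adjusted p = 0.372 with an estimated correlation), and Vegfa, Ndrg1, Ddit4 and Ier3 fell adjusted over the list alone. Vegfa, the endothelial growth factor, had 78.0 ± 3.095 CPM in LKR13KL and 446 ± 93.9 in LKR13K, and Il1b, the inflammatory cytokine, 1235 ± 213 and 7446 ± 3387 (edgeR adjusted p = 0.0979 for each). Cell cycle genes were higher in 14 of 16 members (camera adjusted p = 9.2e-08, and adjusted p = 0.372 with an estimated correlation), with Stmn1, Mcm5 and Birc5 higher adjusted over the list alone. Oxidative phosphorylation genes were higher in 30 of 32 (camera adjusted p = 3.86e-05, and adjusted p = 0.478 with an estimated correlation). These 4 lists were called in all 6 fits that left out 1 library. By edgeR 0 genes passed in cluster 8, with 627 at an unadjusted p under 0.05. Without LKR13K replicate 1 edgeR called 8, and without LKR13K replicate 2 it called 4, all lower, among them Il1b (adjusted p = 0.036). Median UMI counts in this cluster were 3584 and 2682 in LKR13K and 1811 and 5537 in LKR13KL.

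In cluster 9, the Ccl24 and Mmp12 cluster, Vcam1, Gpnmb and H2-M2 were lower and Ly6a and Ifitm1 higher in LKR13KL. Vcam1, a leukocyte adhesion molecule, fell from 289 ± 122 to 26.2 ± 16.9 CPM (log2 fold change −3.88 ± 0.56, edgeR adjusted p = 0.0157), and Gpnmb, a glycoprotein of lipid-laden macrophages, by 3.91 on the log2 scale (edgeR adjusted p = 0.0491). H2-M2, a nonclassical MHC class I gene, fell by 3.47 (edgeR adjusted p = 0.0359). Ly6a rose from 80.0 ± 38.2 to 402 ± 148 CPM and Ifitm1, an antiviral membrane protein, from 308 ± 85.3 to 1344 ± 98.7 CPM (log2 fold changes 2.38 ± 0.42 and 2.11 ± 0.36, edgeR adjusted p = 0.0359 for each). Apoe, the lipid transport protein, and Cfb, complement factor B, also fell, by 3.29 and 3.06 on the log2 scale (edgeR adjusted p = 0.0162 and 0.0491), and both were chosen after their values were seen. In all, 7 of 7429 genes passed, 2 higher and 5 lower, with 384 at an unadjusted p under 0.05. The count was 30 without LKR13K replicate 1, 12 without LKR13K replicate 2, 0 without LKR13KL replicate 2 and 15 without LKR13KL MCT4KO replicate 1. Without LKR13KL replicate 2, the log2 fold changes were −2.94 for Vcam1 (adjusted p = 0.601), −2.26 for H2-M2 (0.942), −3.33 for Gpnmb (0.942), −2.57 for Cfb (0.942), −2.49 for Apoe (0.0958), 2.04 for Ifitm1 (0.243) and 2.74 for Ly6a (0.0958). Without LKR13K replicate 2 they were −1.74 for Gpnmb (0.964), −2.601 for Cfb (0.424) and 1.88 for Ly6a (0.25). Without LKR13KL replicate 1 they were −4.08 for Gpnmb (0.134), −3.19 for Cfb (0.0974), 1.97 for Ly6a (0.181) and 2.19 for Ifitm1 (0.0791), and without LKR13K replicate 1 1.87 for Ifitm1 (0.0586). The lysosome and lipid handling list was lower in 14 of 17 members (camera adjusted p = 1.25e-09, and adjusted p = 0.419 with an estimated correlation), and Apoe, Gpnmb, Spp1, Trem2, Lpl and Ctsb fell adjusted over the list alone. It was called in all 6 fits without 1 library. Extracellular matrix and remodelling genes were lower in 7 of 10 (camera adjusted p = 1.86e-06, and adjusted p = 0.419 with an estimated correlation). The members lower adjusted over the list alone were the proteases Mmp2, Mmp9 and Mmp13 and the inhibitor Timp2, and the list was lost without LKR13KL replicate 2 (0.0741). Apoe lies on chromosome 7 from 19696109 to 19699188, Vcam1 on chromosome 3 from 116109949 to 116129688 and Ly6a on chromosome 15 from 74994877 to 74998031 (GRCm38).

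Among the other classes, endothelial cell-like cells of LKR13KL showed higher cell cycle genes, 19 of 20 members (camera adjusted p = 9.16e-12, and adjusted p = 0.265 with an estimated correlation). Adjusted over the list alone 6 rose, Cenpf, Nusap1, Ube2c, Ccna2, Cdk1 and Birc5, and Ube2c, a ubiquitin-conjugating enzyme of mitosis, had 127 ± 6.85 CPM against 13.2 ± 9.89. Fibroblast-like cells had higher glycolysis and lactate transport genes (17 of 21) and hypoxia response genes (16 of 20), each with a camera adjusted p of 0.00106 and an adjusted p = 0.716 with an estimated correlation. Monocyte-like cells had lower alternative (M2-type) genes, 11 of 15 (camera adjusted p = 0.00028, and adjusted p = 0.442 with an estimated correlation), with Ccl22, a chemokine for regulatory T cells, lower adjusted over the list alone. These 4 lists held in all 6 fits without 1 library. By edgeR 0 genes passed in endothelial cell-like cells (457 at an unadjusted p under 0.05, and 5 called without LKR13K replicate 1) and 0 in monocyte-like cells (166).

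Neutrophil-like cells had 4 genes called lower and fibroblast-like cells 2. For neutrophil-like cells the count was 2 without LKR13K replicate 1, 18 without LKR13KL replicate 2 and 13 and 11 without LKR13KL MCT4KO replicates 1 and 2. For fibroblast-like cells it was 0 without any 1 of the LKR13K or LKR13KL samples and 1 without either LKR13KL MCT4KO sample. In neutrophil-like cells these were Rrm2 (ribonucleotide reductase), Hamp (hepcidin), Sprr1a (a cornified envelope protein) and Rpl13a, and in fibroblast-like cells Meox1, a homeobox factor, and the immunoglobulin gene Igkc. Rpl13a and Igkc are of kinds outside the naming rule and were chosen after their values were seen. Sprr1a was not particular to neutrophil-like cells. Outside fibroblast-like and endothelial cell-like cells it was above 0 in all 23 values per class and library of LKR13K and in 8 of 21 of LKR13KL. Meox1 stood at 2.27 ± 0.332 CPM in LKR13KL and 34.3 ± 2.22 in LKR13K (log2 fold change −3.86 ± 0.33, edgeR adjusted p = 0.034). It was called in 0 of 6 fits without 1 library, with an adjusted p of up to 0.479 without LKR13K replicate 2, while its log2 fold change stayed between −4.035 and −3.74. Rrm2 and Hamp rested on single cells: 1 cell of LKR13K replicate 1 held 94.6% of the 56 Rrm2 counts of the LKR13K group, and another held 73.5% of its 34 Hamp counts. For Igkc, 1 fibroblast-like cell of that library held 626 of 914 counts, and 1 of LKR13K replicate 2 held 276 of the 277 counts there. Without the cells of LKR13K replicate 1 named here, a choice made after the data were seen, 0 genes were called in either class by edgeR. The Igkc cell of LKR13K replicate 2 was not left out, so its 276 counts stayed in. The log2 fold changes of the genes held by the cells left out went from −7.61 to −3.74 for Rrm2, from −6.91 to −5.23 for Hamp and from −10.585 to −9.015 for Igkc (adjusted p = 0.987, 0.987 and 0.748 without the cells). Those cells do not hold Sprr1a, Rpl13a and Meox1, whose log2 fold changes were −6.96 ± 1.36, −7.09 ± 1.51 and −3.86 ± 0.33 with the cells and −7.01 ± 1.28, −7.07 ± 1.498 and −3.86 ± 0.32 without them (adjusted p = 0.0661, 0.146 and 0.0644). Without LKR13K replicate 1, the log2 fold changes were −4.697 for Rrm2 and −4.14 for Hamp (adjusted p = 0.999 each), −7.39 for Sprr1a (0.0566) and −9.98 for Igkc (0.0629). Without LKR13K replicate 2 they were −4.41 for Rpl13a (1), −6.24 for Sprr1a (0.481) and −11.03 for Igkc (0.103). Without LKR13KL replicate 1 they were −6.83 for Hamp and −6.85 for Sprr1a (0.203 each), −6.96 for Rpl13a (0.16) and −12.19 for Igkc (0.285), and without LKR13KL replicate 2 −10.14 for Igkc (0.187). Rrm2, Hamp, Sprr1a and Rpl13a had a count of 0 in both LKR13KL samples. Rpl13a stood at 13.9 CPM in LKR13K replicate 1 and 182 in replicate 2, and in T cell-like cells at 556 and 3820. The pseudogene Rpl13a-ps1 was at 0 in LKR13K replicate 2 alone and was left out. Over the 8 classes edgeR called 26 genes in 57734 tests, 4 higher and 22 lower, with 3164 at an unadjusted p under 0.05. The total was 76 without LKR13K replicate 1, 15 without LKR13KL replicate 1 and 62 without LKR13KL replicate 2. DESeq2 called 72 genes, 5 of them shared with edgeR.

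**Figure D3:**
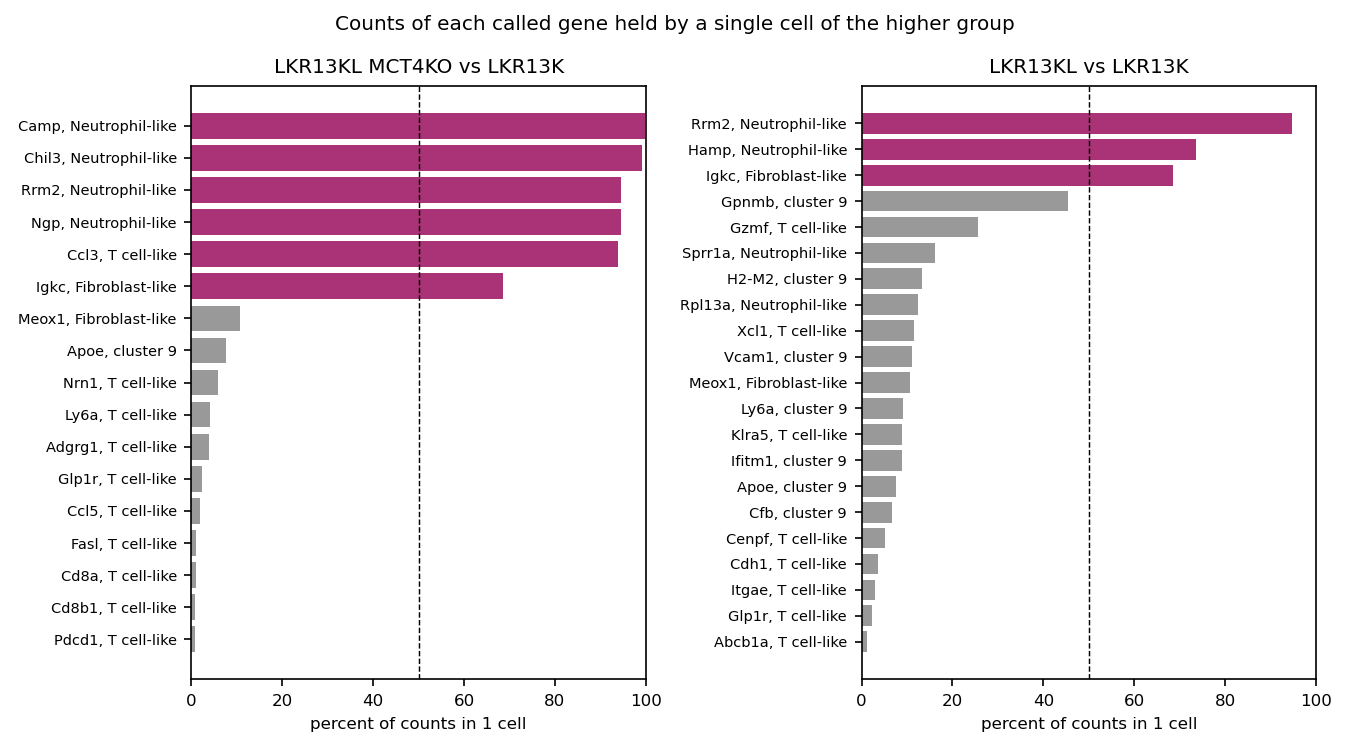
Percent of a called gene's counts in its higher group that lay in 1 cell (x axis), for the genes called (y axis, with the cell class) between LKR13KL MCT4KO and LKR13K (left) and between LKR13KL and LKR13K (right), leaving out T cell receptor segments and predicted genes. Bars start at 0, the dashed line marks 50%, and coloured bars lie above it, up to 99.8% for Camp.

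The second comparison, LKR13KL MCT4KO against LKR13KL, asks how removing the lactate exporter from Stk11-deficient tumour cells accompanies differences in host cells. T cell-like cells made up 9.77% ± 7.55 of LKR13KL MCT4KO cells and 14.9% ± 13.1 of LKR13KL cells, neutrophil-like cells 13.6% ± 0.473 and 10.3% ± 3.85, pericyte-like cells 1.57% ± 0.486 and 1.02% ± 0.125, and macrophage-like cells 16.05% ± 0.794 and 17.5% ± 0.713. The groups were apart for 3 of 17 classes and clusters, neutrophil-like and pericyte-like cells higher and macrophage-like cells lower, where chance gives 33.3%. The smallest adjusted p of the exact permutation test was 1. For T cell-like cells the difference of −5.17 percentage points turned to 4.1 without LKR13KL replicate 1, and for macrophage-like cells the difference turned to 1.159 with clustering at resolution 2.0. The macrophage-like separation is of the class without clusters 8 and 9. In LKR13KL MCT4KO replicates 1 and 2 cluster 8 made up 3.96% and 7.375% of cells, against 3.27% and 6.40% in LKR13KL. Cluster 9 made up 1.78% and 14.16% against 1.04% and 17.98%. No plasma cell-like cell was found among the 678 cells of LKR13KL MCT4KO replicate 2, which allows up to 0.442%.

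Cytotoxic genes were lower and the regulatory T cell list higher in T cell-like cells of LKR13KL MCT4KO tumours. Of 20 cytotoxic effector genes 17 were lower and 3 higher (camera adjusted p = 1.61e-07, and adjusted p = 0.385 with an estimated correlation). Adjusted over the list alone, Prf1 (perforin) and Ccl5, a T cell chemokine, fell, and Ccl3 rose. Prf1 had 28.5 ± 9.22 CPM in LKR13KL MCT4KO and 77.0 ± 19.9 in LKR13KL, and Ccl5 had 478 ± 330 and 1746 ± 252 (log2 fold changes −1.55 ± 0.42 and −1.79 ± 0.40), and neither passed over all genes. The Ccl3 value came from 1 cell of LKR13KL MCT4KO replicate 1 that held 265 of 282 counts, and its log2 fold change of 2.92 turned to −0.32 without that library. Cd8a and Cd8b1, the chains of the CD8 coreceptor, had 63.5 ± 50.3 and 62.2 ± 48.4 CPM against 228 ± 129 and 271 ± 118 (edgeR adjusted p = 0.519 for Cd8b1). All 13 regulatory T cell genes were higher (camera adjusted p = 8.79e-05, and adjusted p = 0.561 with an estimated correlation), and Il2ra, the high-affinity interleukin-2 receptor chain, rose adjusted over the list alone (457 ± 204 against 170 ± 4.38 CPM). This list was not called and turned lower without LKR13KL replicate 1 (0.506). Naive and memory genes were higher in 8 of 10 members, with Sell (L-selectin) higher adjusted over the list alone (camera adjusted p = 0.0472, and adjusted p = 0.587 with an estimated correlation), and the call was lost without LKR13KL replicate 1 (0.641) or LKR13KL MCT4KO replicate 1 (0.636).

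Cluster 4, the Cd8a cluster, made up 7.69% and 10.0% of T cell-like cells in LKR13KL MCT4KO replicates 1 and 2 and 29.5% and 10.9% in LKR13KL, and cluster 10, the Foxp3 cluster, 37.1% and 40.0% against 13.2% and 47.8%. LKR13KL MCT4KO replicate 2 held 30 T cell-like cells. The exhaustion and checkpoint list had 9 members higher and 7 lower (camera adjusted p = 0.706), and cell cycle genes 10 and 10 (camera adjusted p = 0.626). Mitochondrially encoded transcripts, which follow RNA and cell quality, were lower in 10 of 13 (camera adjusted p = 0.0063, and adjusted p = 0.385 with an estimated correlation), and this was lost without LKR13KL replicate 1 (0.108) or LKR13KL MCT4KO replicate 1 (0.0705). The list of free RNA, whose 6 members tested here include Cd3e, a gene of T cells themselves, was lower in 4 of 6 (camera adjusted p = 0.0414, and adjusted p = 0.561 with an estimated correlation), with Krt8 lower adjusted over the list alone, and was lost without LKR13KL replicate 2 (0.813) or LKR13KL MCT4KO replicate 1 (0.883). By edgeR 0 of 7851 genes passed in this class, with 267 at an unadjusted p under 0.05. Over the 8 classes edgeR called 0 genes, with 1184 at an unadjusted p under 0.05, DESeq2 called 1 and limma with a pseudocount of 0.1 called 0. The edgeR total was 11 without LKR13KL replicate 2, 3 without LKR13K replicate 2, 2 without LKR13KL replicate 1, 2 without LKR13KL MCT4KO replicate 2 and 1 without LKR13K replicate 1. The smallest adjusted p over the classes was 0.0649, in T cell-like cells.

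Macrophage-like cells of LKR13KL MCT4KO had higher interferon-response genes and lower cell cycle genes. Type I interferon response genes were higher in 18 of 19 members and interferon gamma response genes in 15 of 16 (camera adjusted p = 1.63e-06 and 0.000213). Both had an adjusted p = 0.59 with an estimated correlation. Isg15, a ubiquitin-like interferon effector, had 508 ± 180 CPM in LKR13KL MCT4KO and 214 ± 77.7 in LKR13KL, and Irf7, an interferon regulatory factor, 146 ± 31.9 and 73.4 ± 3.97. The log2 fold change of Irf7 turned to −0.025 with a mean over cells of linear values and to −0.124 with clustering at resolution 0.5. Without LKR13KL MCT4KO replicate 1 the type I list was not called (0.719) and the interferon gamma list turned lower (0.256), and the interferon gamma list was also lost without LKR13KL replicate 2 (0.359). Cell cycle genes were lower in 15 of 16 members (camera adjusted p = 1.63e-06, and adjusted p = 0.59 with an estimated correlation), in all 6 fits without 1 library. Chemokines for neutrophils and monocytes were lower in 12 of 17 (camera adjusted p = 0.0059, and adjusted p = 0.59 with an estimated correlation), with Cxcl1 at 622 ± 142 against 1195 ± 145 CPM and Cxcl2 at 4303 ± 623 against 8014 ± 2142. The log2 fold change of Cxcl2 turned to 0.159 with all myeloid clusters in the class. That list was lost without LKR13KL MCT4KO replicate 2 (0.0598). Alternative (M2-type) genes were higher in 10 of 17 (camera adjusted p = 0.0393, and adjusted p = 0.59 with an estimated correlation). Adjusted over the list alone Ccl24 and Ccl17 rose, with Ccl24, an eosinophil chemokine, at 709 ± 268 against 194 ± 5.55 CPM (log2 fold change 1.86 ± 0.35). Without LKR13KL replicate 2, LKR13KL MCT4KO replicate 1 or LKR13KL MCT4KO replicate 2 this list had an adjusted p of 0.261, 0.226 and 0.0584. Classical (M1-type) genes were higher in 13 of 15 (camera adjusted p = 0.00486, and adjusted p = 0.59 with an estimated correlation). That call was lost without LKR13KL replicate 2 (0.854), and the list turned lower without LKR13KL MCT4KO replicate 1 (0.256). Mitochondrially encoded transcripts were lower in 12 of 13 (camera adjusted p = 0.00488, and adjusted p = 0.59 with an estimated correlation), which was lost without LKR13KL replicate 1 (0.0593) or LKR13KL MCT4KO replicate 2 (0.397). Glycolysis and lactate transport genes had 13 members higher and 8 lower (camera adjusted p = 0.441). No gene passed edgeR in this class, with 85 at an unadjusted p under 0.05. Cluster 2 made up 54.7% and 77.1% of macrophage-like cells in LKR13KL MCT4KO against 45.8% and 58.2% in LKR13KL, and their median UMI counts were 1760 and 1191 against 3053.5 and 2396.

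Monocyte-like cells also had higher type I interferon response genes, 18 of 19 (camera adjusted p = 1.32e-07, and adjusted p = 0.633 with an estimated correlation), which turned without LKR13KL MCT4KO replicate 1 (0.171). In fibroblast-like cells glycolysis and lactate transport genes were higher in 19 of 21 members (camera adjusted p = 5.8e-06, and adjusted p = 0.437 with an estimated correlation), in all 6 fits without 1 library. Ldha (lactate dehydrogenase) had a log2 fold change of 0.34 ± 0.15 and Slc2a1, a glucose transporter, 0.51 ± 0.18. Hypoxia response genes were higher in 17 of 20 (camera adjusted p = 0.000102, and adjusted p = 0.424 with an estimated correlation) and were lost without LKR13KL MCT4KO replicate 1 (0.0983). Extracellular matrix genes of this class with the smallest p included Col4a1, a basement membrane collagen, at 421 ± 116 against 583 ± 35.6 CPM, and Tnc (tenascin C) at 2451 ± 245 against 1817 ± 53.7, and neither passed. In cluster 8 Ccl24 had 3639 ± 3162 CPM in LKR13KL MCT4KO and 239 ± 198 in LKR13KL, and Arg1, which degrades arginine, had 1598 ± 315 and 547 ± 127, and neither passed. In cluster 9 Cxcl9, a chemokine for effector T cells, had 299 ± 102 against 118 ± 9.70, and in endothelial cell-like cells Gja5, a gap junction protein of arteries, had 83.6 ± 33.5 against 12.5 ± 7.05, and neither passed.

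The third comparison, LKR13KL MCT4KO against LKR13K, spans both alterations, and its genes lay outside the naming rule and were chosen after their values were seen. In T cell-like cells of LKR13KL MCT4KO Cd8a, Cd8b1, Ccl5, Fasl and Pdcd1 were lower and Ly6a higher. The log2 fold changes were −2.82 for Cd8a, −2.66 for Cd8b1, −3.51 for Ccl5, −2.32 for Fasl, the death receptor ligand, −2.07 for Pdcd1 and 1.68 for Ly6a (edgeR adjusted p = 0.0278, 0.0278, 0.016, 0.0278, 0.0437 and 0.0188). Ccl3 was also called higher, in the 1 cell named above. The cytotoxic effector list had 9 members higher and 11 lower and was called lower (camera adjusted p = 1.15e-06, and adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone 9 fell, among them Fasl, Ccl5 and Prf1, and Ccl3, Gzmf and Ifng rose. Mitochondrially encoded transcripts were lower in 12 of 13 (camera adjusted p = 0.00572, and adjusted p = 0.336 with an estimated correlation), which was lost without LKR13K replicate 1 (0.0638). The same list of free RNA was lower in 4 of 6 (camera adjusted p = 0.0183, and adjusted p = 0.427 with an estimated correlation), with Krt8 and Krt18 lower adjusted over the list alone, as was Cd3e, which is no sign of other cells in this class. The call was lost without LKR13KL MCT4KO replicate 1 (0.745). Cluster 4 made up 7.69% and 10.0% of T cell-like cells in LKR13KL MCT4KO and 34.6% and 52.4% in LKR13K. The class had 11 calls, 2 higher and 9 lower, against 2 by limma with a pseudocount of 0.1 and 0 by edgeR with the symbols as deposited. They numbered 1 without LKR13K replicate 2, 2 without LKR13KL MCT4KO replicate 1, 1 without LKR13KL MCT4KO replicate 2, 30 without LKR13K replicate 1, 46 without LKR13KL replicate 1 and 50 without LKR13KL replicate 2. Without LKR13KL MCT4KO replicate 1 the log2 fold changes were −4.33 for Cd8a (adjusted p = 0.147), −4.15 for Cd8b1 (0.143), −4.06 for Fasl (0.196), −1.69 for Pdcd1 (0.555) and 1.74 for Ly6a (0.147). Without LKR13KL MCT4KO replicate 2 they were −2.504 (0.134), −2.36 (0.127), −2.14 (0.127), −2.35 (0.128) and 1.59 (0.127) in the same order, and −3.04 for Ccl5 (0.122). Without LKR13K replicate 2 they were −2.86 (0.0681), −2.65 (0.0681), −2.22 (0.142), −1.89 (0.224) and 1.56 (0.242) in that order. Ccl3 had 0.67 without LKR13KL MCT4KO replicate 1 (0.912), 3.18 without LKR13K replicate 1 (0.12) and 4.58 without LKR13K replicate 2 (0.0681). Without the single cells that held most of a called gene the calls in T cell-like cells numbered 24. Apoe fell in cluster 9 by 3.71 (edgeR adjusted p = 0.00858), and had −3.42 without LKR13KL MCT4KO replicate 2 (0.296). In neutrophil-like cells Camp, Chil3, Ngp and Rrm2 were called lower, with log2 fold changes of −6.47, −9.695, −12.08 and −7.61 (edgeR adjusted p = 0.0204, 0.00995, 0.00995 and 0.0204). Without the single cell that held most of their counts, Camp turned to 1.665, and Chil3 had −3.196, Ngp −8.18 and Rrm2 −3.74 (adjusted p = 1 each). Without LKR13K replicate 1 Camp had 1.65, Rrm2 −4.697 and Chil3 and Ngp 0 (adjusted p = 1 each), and Rrm2 had an adjusted p of 0.197 without LKR13KL MCT4KO replicate 1. Over the 8 classes 18 genes were called, 2 higher and 16 lower, with 3294 at an unadjusted p under 0.05, and DESeq2 called 50, of which 9 were shared. The edgeR total was 57 without LKR13K replicate 1, 61 without LKR13KL replicate 1, 68 without LKR13KL replicate 2 and 7 without LKR13KL MCT4KO replicate 1. For shares the groups were apart for 12 of 17 classes and clusters, 6 higher and 6 lower, and no difference could pass the exact permutation test, whose smallest adjusted p was 0.472.

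Whether the second alteration turned back the first was asked across genes, which are not independent replicates. The log2 fold changes of the first 2 comparisons were negatively correlated in all 8 classes, with Pearson r from −0.443 in cluster 9 to −0.184 in fibroblast-like cells. Both comparisons share the LKR13KL samples with opposite sign, and 50 simulations of unchanged groups gave r from −0.557 in T cell-like cells to −0.405 in macrophage-like cells. The observed covariance exceeded the simulated covariance in all 8 classes, by 0.0152 in cluster 8 to 0.0592 in monocyte-like cells. The simulations drew every library independently, whereas LKR13KL and LKR13KL MCT4KO libraries of the same number deviated together. The correlation of their deviations ran from 0.095 in cluster 9 to 0.433 in fibroblast-like cells. Shared deviations of this kind raise the covariance, so the excess cannot decide for or against a reversal. In T cell-like cells the covariance was −0.0614 against −0.0786 ± 0.0016 (SD of simulations).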

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

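The tests weighed in this part were all chosen after the results were seen.

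In LKR13K replicate 2, 0.372% of the counts lay on genes left out of every comparison, against 0.1% to 0.115% in the other 5 libraries. These genes were left out because that library had been counted with another gene annotation. Of the 315 genes left out, 231 were picked for being counted in that library alone. Its higher share therefore follows largely from the choice and is no separate signal.

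In T cell-like cells 11 genes, among them Itgae, Cdh1, Xcl1 and Glp1r, were lower in LKR13KL than in LKR13K. A shift of the class between its clusters, with levels within clusters as in LKR13K, would account for 0 of the 11 within 2 SE, which argues against it as the whole cause. The gene annotation of LKR13K replicate 2 is argued against too, since 7 of the 11 were still called lower without that library. Those 7 were Itgae, Cdh1, Glp1r and T cell receptor segments, a kind that the annotation step did not check. Xcl1, Abcb1a and Klra5 were not among them, so the argument does not cover these 3. With the gene symbols left as deposited edgeR called 0 genes in this class, so the calls depend on the annotation step. Without LKR13KL replicate 1 the calls of Itgae, Cdh1, Xcl1 and Glp1r were lost with log2 fold changes of −2.16, −8.15, −8.71 and −8.66, the last 3 against a count of 0, and limma with a pseudocount of 0.1 called 0 genes. Loss of Stk11 in the tumour line is the difference in the labels, but the host cells of 2 samples per group cannot separate it from other differences between tumours.

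In neutrophil-like and fibroblast-like cells 8 of the 12 calls against LKR13K had most of their counts in single cells. The genes were found in at most 15.7% of the number of cells an even spread would give. They were picked because 1 cell held most of their counts, which holds this value down. The way they were picked still allowed each of them 53.5% or more. For these genes the values argue against free RNA, spread evenly over the droplets, as the source of most counts. Whether it brought the remaining counts was not tested. Without the single cells of LKR13K replicate 1 that hold most counts of a gene, 0 calls were left in the 2 classes, but the 8 were picked for those cells, so this refit decides nothing. The log2 fold changes it gave were −9.015 for Igkc, −5.23 for Hamp and −3.74 for Rrm2 in LKR13KL, and −10.92 for Igkc, 1.665 for Camp, −3.196 for Chil3, −8.18 for Ngp and −3.74 for Rrm2 in LKR13KL MCT4KO. A cell of LKR13K replicate 2 that held most Igkc counts of that library was not left out. What the cells left out are stays open, and no biological explanation was tested. The cell left out for Igkc held 6 of 8 plasma cell and 12 of 13 fibroblast markers, with 3.57% and 3.31% of its UMIs on them. The cell left out for Rrm2 also held most counts of Camp, Chil3 and Ngp. It held 9 of 13 neutrophil markers and 27190 UMIs, 20.2 times the median of its class in its library.

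Class shares differed between the 2 libraries of a group in the same direction in all 3 groups for 12 of 17 classes and clusters, 7 lower and 5 higher in replicate 2. The highest number with another matching of the libraries was 3. A batch shared by libraries of the same replicate number cannot be told apart from chance here, because 4 matchings allow no smaller share than 25%. No biological explanation was tested.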

How the results depend on the processing

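Of 774 alternative counts of called genes 507 lay within 1.5 times the value reported and 267 did not. Of 957 alternative results for lists 603 kept their direction and side of the threshold, 325 lost the call and 29 turned. Of 338 for shares 297 were kept, 37 turned and 4 gained a call, and of 5109 for single genes 4697 were kept, 166 gained a call, 215 lost it and 31 turned. On simulated data edgeR called from 0% to 22.4% of genes changed 2-fold over the classes, and from 31.8% to 98.5% of those changed 8-fold. Leaving out the cells a doublet caller marks, chosen before the data were examined, was not run, because the caller marked 7 cells, and the 5% with the highest scores were left out instead. For every result below that moved or turned the cause was not tested.

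For LKR13KL against LKR13K, the 26 calls, 13 in T cell-like and 0 in macrophage-like cells, became 1 in all and 0 in T cell-like (limma, pseudocount 0.02), 8 in all and 1 in T cell-like (limma, pseudocount 0.5), 473 in all, 239 in T cell-like and 29 in macrophage-like (no filter), 1 in all and 1 in T cell-like (filter at 0.5 per 10000), 4 in T cell-like (limma, mean of log values), 0 in T cell-like and 3 in macrophage-like (limma, mean over cells of linear values). Other settings gave 6 in all and 0 in T cell-like (limma, median centring), 41 in all and 31 in T cell-like (robust empirical Bayes), 10 in all (no trend), 1 in macrophage-like (resolution 2.0), 4 in T cell-like (equal cell numbers), 681 in all and 603 in T cell-like (limma, weights by the number of cells). The rest gave 7 in all and 0 in T cell-like (limma, pseudocount 0.1), 72 in all and 7 in macrophage-like (DESeq2), 6 in T cell-like (RLE scaling), 16 in all (filterByExpr), 2 in all and 0 in T cell-like (symbols as deposited), 16 in all (without the top 5% of doublet scores).

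For LKR13KL MCT4KO against LKR13KL, the 0 calls became 71 in all, 43 in T cell-like and 2 in macrophage-like (no filter), 3 in all (limma, mean of log values), 2 in all (limma, mean over cells of linear values). Other settings gave 1 in all and 1 in T cell-like (only the 4 samples of the 2 groups), 4 in all (resolution 2.0), 4 in all and 3 in T cell-like (equal cell numbers). The rest gave 1 in all (DESeq2), 4 in all (no scaling), 1 in all and 1 in T cell-like (filterByExpr).

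For LKR13KL MCT4KO against LKR13K, the 18 calls, 11 in T cell-like and 0 in macrophage-like cells, became 2 in all and 0 in T cell-like (limma, pseudocount 0.02), 7 in T cell-like (limma, pseudocount 0.5), 481 in all, 235 in T cell-like and 26 in macrophage-like (no filter), 3 in all and 3 in T cell-like (filter at 0.5 per 10000), 36 in all (limma, mean of log values), 4 in T cell-like (limma, mean over cells of linear values), 5 in all and 2 in T cell-like (limma, median centring). Other settings gave 40 in all and 38 in T cell-like (robust empirical Bayes), 66 in all and 49 in T cell-like (only the 4 samples of the 2 groups), 17 in T cell-like (resolution 0.5), 1 in macrophage-like (resolution 2.0), 32 in all and 18 in T cell-like (equal cell numbers), 35 in all and 27 in T cell-like (limma, weights by the number of cells), 6 in all and 2 in T cell-like (limma, pseudocount 0.1). The rest gave 50 in all and 17 in T cell-like (DESeq2), 24 in T cell-like (filterByExpr), 4 in all and 0 in T cell-like (symbols as deposited), 24 in T cell-like (without the top 5% of doublet scores), 24 in T cell-like (without cells holding most of a called gene).

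Leaving out 1 library at a time, with the lone sample of a group assumed to vary like the others, the calls ranged from 15 (without LKR13KL replicate 1) to 76 (without LKR13K replicate 1) in all classes for LKR13KL against LKR13K, 2 (without LKR13KL replicate 1) to 44 (without LKR13KL replicate 2) in T cell-like cells for LKR13KL against LKR13K, 0 (without LKR13K replicate 2) to 4 (without LKR13K replicate 1) in macrophage-like cells for LKR13KL against LKR13K, 0 (without LKR13KL MCT4KO replicate 1) to 11 (without LKR13KL replicate 2) in all classes for LKR13KL MCT4KO against LKR13KL. They ranged from 0 (without LKR13KL replicate 1) to 1 (without LKR13K replicate 1) in T cell-like cells for LKR13KL MCT4KO against LKR13KL, 7 (without LKR13KL MCT4KO replicate 1) to 68 (without LKR13KL replicate 2) in all classes for LKR13KL MCT4KO against LKR13K, 1 (without LKR13K replicate 2) to 50 (without LKR13KL replicate 2) in T cell-like cells for LKR13KL MCT4KO against LKR13K, 0 (without LKR13K replicate 2) to 2 (without LKR13K replicate 1) in macrophage-like cells for LKR13KL MCT4KO against LKR13K. The 38 lists called for LKR13KL MCT4KO against LKR13KL ranged from 34 (without LKR13K replicate 1) to 71 (without LKR13KL replicate 1).

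Some named genes turned, in log2 fold change. In T cell-like cells for LKR13KL against LKR13K Ccnb1 -0.78 (equal cell numbers). In T cell-like cells for LKR13KL MCT4KO against LKR13KL Ccl3 -0.075 (without the top 5% of doublet scores) and -0.68 (without cells that hold most of a called gene), Krt18 0.03 (limma, mean of log values). In macrophage-like cells for LKR13KL against LKR13K Chil3 -3.17 (resolution 0.5), -0.64 (resolution 2.0), -2.94 (macrophage class with clusters 8 and 9) and -2.001 (macrophage class with all myeloid clusters), P4ha1 -0.29 (resolution 0.5), -0.61 (resolution 2.0), -0.069 (macrophage class with clusters 8 and 9) and -0.13 (macrophage class with all myeloid clusters), Hspa1a 0.15 (limma, mean of log values), 0.11 (resolution 0.5), 0.058 (resolution 2.0) and 1.502 (without the top 5% of doublet scores). There too, Hsph1 0.031 (limma, mean of log values). In macrophage-like cells for LKR13KL MCT4KO against LKR13KL Cryab -0.006 (limma, mean of log values) and -0.17 (limma, mean over cells of linear values), Cxcl2 0.16 (macrophage class with all myeloid clusters), Hamp 0.37 (macrophage class with all myeloid clusters). There too, Tnf -0.03 (limma, mean of log values) and -0.17 (resolution 2.0), Irf7 -0.025 (limma, mean over cells of linear values) and -0.12 (resolution 0.5). In endothelial cell-like cells for LKR13KL MCT4KO against LKR13KL Cd14 0.699 (without the top 5% of doublet scores), Sdc1 0.042 (limma, mean over cells of linear values) and 0.299 (without the top 5% of doublet scores). Leaving out 1 library in T cell-like cells, Gzmf ranged from -4.94 (without LKR13KL replicate 1) to 4.12 (without LKR13KL replicate 2) for LKR13KL against LKR13K, Ccl3 ranged from -0.32 (without LKR13KL MCT4KO replicate 1) to 3.73 (without LKR13KL replicate 1) for LKR13KL MCT4KO against LKR13KL, Krt18 ranged from -2.303 (without LKR13KL MCT4KO replicate 2) to 0.395 (without LKR13KL MCT4KO replicate 1) for LKR13KL MCT4KO against LKR13KL. The lowest value of Gzmf sets a count of 0 in LKR13KL replicate 2 against LKR13K levels below what that 0 allows, so it shows no direction.

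Share differences that turned, in percentage points or on the logit scale under limma, were for LKR13KL against LKR13K macrophage-like cells -0.235 (resolution 2.0), and for LKR13KL MCT4KO against LKR13KL macrophage-like cells 1.16 (resolution 2.0), monocyte-like cells 0.0924 (resolution 2.0), cluster 3 0.253 (immune classes as the denominator), mast cell-like cells -0.0848 (without the top 5% of doublet scores), cluster 3 0.379 (limma on logit shares), cluster 9 0.135 (limma on logit shares). Without 1 library, shares for LKR13KL against LKR13K ranged over NK cell-like cells -3.04 (without LKR13KL replicate 1) to 0.61 (without LKR13KL replicate 2), neutrophil-like cells -0.577 (without LKR13KL replicate 2) to 4.87 (without LKR13KL replicate 1). Further ranges were cluster 14 -0.621 (without LKR13KL replicate 1) to 1.57 (without LKR13KL replicate 2), cluster 16 -0.0573 (without LKR13KL replicate 2) to 1.81 (without LKR13KL replicate 1). Further ranges were cluster 3 -1.82 (without LKR13KL replicate 1) to 10.71 (without LKR13KL replicate 2), cluster 9 -4.34 (without LKR13KL replicate 2) to 12.61 (without LKR13KL replicate 1). Without 1 library, shares for LKR13KL MCT4KO against LKR13KL ranged over B cell-like cells -0.827 (without LKR13KL replicate 2) to 0.327 (without LKR13KL replicate 1), dendritic cell-like cells -0.903 (without LKR13KL replicate 2) to 0.353 (without LKR13KL replicate 1), endothelial cell-like cells -1.27 (without LKR13KL MCT4KO replicate 2) to 3.38 (without LKR13KL MCT4KO replicate 1), fibroblast-like cells -6.16 (without LKR13KL MCT4KO replicate 2) to 6.89 (without LKR13KL MCT4KO replicate 1), monocyte-like cells -2.1 (without LKR13KL MCT4KO replicate 1) to 1.4 (without LKR13KL MCT4KO replicate 2). Further ranges were NK cell-like cells -0.531 (without LKR13KL replicate 2) to 3.12 (without LKR13KL replicate 1), plasma cell-like cells -0.498 (without LKR13KL replicate 2) to 0.0342 (without LKR13KL replicate 1), T cell-like cells -14.44 (without LKR13KL replicate 2) to 4.1 (without LKR13KL replicate 1), cluster 14 -1.15 (without LKR13KL MCT4KO replicate 1) to 3.4 (without LKR13KL MCT4KO replicate 2), cluster 16 -0.326 (without LKR13KL replicate 1) to 1.55 (without LKR13KL replicate 2). Further ranges were cluster 3 -6.27 (without LKR13KL replicate 2) to 6.26 (without LKR13KL replicate 1), cluster 8 -0.874 (without LKR13KL MCT4KO replicate 2) to 2.54 (without LKR13KL MCT4KO replicate 1), cluster 9 -10.01 (without LKR13KL replicate 1) to 6.93 (without LKR13KL replicate 2).

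By camera with an estimated correlation and by fry, 0 of 49, 0 of 38 and 0 of 69 called lists were left in the 3 comparisons. Camera adjusted p-values of lists that turned for LKR13KL against LKR13K were, in cluster 8, type I interferon response 1.57e-06 (without LKR13KL replicate 2) to 0.429 (without LKR13K replicate 2, turned without LKR13KL replicate 1), interferon gamma response 3.27e-15 (without LKR13KL replicate 2) to 0.145 (without LKR13K replicate 2, turned without LKR13KL replicate 1). In cluster 9 they were type I interferon response 2.54e-09 (without LKR13K replicate 2) to 0.9 (without LKR13KL replicate 2, turned without LKR13K replicate 1 and LKR13KL replicate 2). In monocyte-like cells they were cytotoxic effector 9.75e-05 (without LKR13KL replicate 1) to 0.982 (without LKR13KL replicate 2, turned without LKR13KL replicate 2). In neutrophil-like cells they were classical (M1-type) macrophage 3.38e-08 (without LKR13KL replicate 2) to 0.542 (without LKR13KL replicate 1, turned without LKR13KL replicate 1), cytotoxic effector 5.44e-12 (without LKR13KL replicate 2) to 0.145 (without LKR13KL replicate 1, turned without LKR13KL replicate 1), chemokines for neutrophils and monocytes 5.44e-12 (without LKR13KL replicate 2) to 0.433 (without LKR13KL replicate 1, turned without LKR13KL replicate 1). In neutrophil-like cells they were T cell attracting chemokines 4.33e-12 (without LKR13KL replicate 2) to 0.911 (without LKR13KL replicate 1, turned without LKR13KL replicate 1). In fibroblast-like cells they were MHC class I presentation 2.39e-09 (without LKR13KL replicate 2) to 0.42 (without LKR13K replicate 2, turned without LKR13KL replicate 1), type I interferon response 3.44e-08 (without LKR13KL replicate 2) to 0.57 (without LKR13K replicate 2, turned without LKR13KL replicate 1), interferon gamma response 2.39e-09 (without LKR13KL replicate 2) to 0.369 (without LKR13K replicate 2, turned without LKR13KL replicate 1). Camera adjusted p-values of lists that turned for LKR13KL MCT4KO against LKR13KL were, in T cell-like cells, interferon gamma response 7.78e-07 (without LKR13KL replicate 2) to 0.681 (without LKR13KL MCT4KO replicate 1, turned without LKR13KL replicate 1), regulatory T cell 2.78e-22 (without LKR13KL replicate 2) to 0.506 (without LKR13KL replicate 1, turned without LKR13KL replicate 1), free RNA from other cells 0.000795 (without LKR13KL MCT4KO replicate 2) to 0.883 (without LKR13KL MCT4KO replicate 1, turned without LKR13KL MCT4KO replicate 1). In macrophage-like cells they were classical (M1-type) macrophage 7.32e-11 (without LKR13KL MCT4KO replicate 2) to 0.854 (without LKR13KL replicate 2, turned without LKR13KL MCT4KO replicate 1), interferon gamma response 1.29e-14 (without LKR13KL MCT4KO replicate 2) to 0.359 (without LKR13KL replicate 2, turned without LKR13KL MCT4KO replicate 1). In monocyte-like cells they were classical (M1-type) macrophage 2.54e-12 (without LKR13KL MCT4KO replicate 2) to 0.355 (without LKR13KL replicate 2, turned without LKR13KL MCT4KO replicate 1), type I interferon response 1.27e-20 (without LKR13KL MCT4KO replicate 2) to 0.171 (without LKR13KL MCT4KO replicate 1, turned without LKR13KL MCT4KO replicate 1), interferon gamma response 5.53e-20 (without LKR13KL MCT4KO replicate 2) to 0.355 (without LKR13KL replicate 2, turned without LKR13KL MCT4KO replicate 1). In neutrophil-like cells they were classical (M1-type) macrophage 3.19e-09 (without LKR13KL replicate 2) to 0.823 (without LKR13KL MCT4KO replicate 2, turned without LKR13KL replicate 1), MHC class II presentation 5.93e-10 (without LKR13KL replicate 2) to 0.214 (without LKR13KL MCT4KO replicate 2, turned without LKR13KL replicate 1), interferon gamma response 5.34e-09 (without LKR13KL MCT4KO replicate 1) to 0.193 (without LKR13KL MCT4KO replicate 2, turned without LKR13KL replicate 1 and LKR13KL MCT4KO replicate 2). In neutrophil-like cells they were cytotoxic effector 1.58e-11 (without LKR13KL replicate 2) to 0.664 (without LKR13KL MCT4KO replicate 2, turned without LKR13KL replicate 1), T cell attracting chemokines 2.75e-11 (without LKR13KL replicate 2) to 0.599 (without LKR13KL MCT4KO replicate 2, turned without LKR13KL replicate 1). In fibroblast-like cells they were interferon gamma response 7.28e-14 (without LKR13KL MCT4KO replicate 2) to 0.063 (without LKR13K replicate 2, turned without LKR13KL replicate 2 and LKR13KL MCT4KO replicate 1), cell cycle 1.77e-23 (without LKR13KL MCT4KO replicate 1) to 0.131 (without LKR13KL replicate 1, turned without LKR13KL MCT4KO replicate 2).

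The excess of the covariance between the first 2 comparisons over its simulated value stayed positive and moved to 0.0227 in T cell-like cells, 0.0297 in cluster 9, 0.0829 in monocyte-like cells, 0.0913 in neutrophil-like cells, 0.0423 in fibroblast-like cells, 0.0308 in endothelial cell-like cells (genes with a mean of at least 0.5 per 10000). With 1 LKR13KL library in each comparison the covariance itself was taken, with no simulated value subtracted. As the mean over both placements of the LKR13KL libraries, this covariance was 0.0394 in T cell-like cells, 0.0261 in macrophage-like cells and 0.0754 in monocyte-like cells. It was 0.0757 in neutrophil-like cells, 0.0418 in fibroblast-like cells and 0.0299 in endothelial cell-like cells.

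The replicate numbers of the groups match, but the labels do not say what a number stands for, and samples of the same number did not deviate together in every pair of groups. The correlation of their deviations from the group means ran from -0.114 to 0.131 between LKR13K and the other groups and from 0.095 to 0.433 between LKR13KL and LKR13KL MCT4KO. With the number as a replicate block, edgeR called 68 genes for LKR13KL against LKR13K, 5 for LKR13KL MCT4KO against LKR13KL (1 in T cell-like cells) and 34 for LKR13KL MCT4KO against LKR13K. Limma on logit shares with the replicate block called, for LKR13KL against LKR13K, B cell-like cells -1.86 (adjusted p = 0.00168), mast cell-like cells -2.201 (adjusted p = 0.000292), plasma cell-like cells -2.59 (adjusted p = 4.82e-05), T cell-like cells -1.31 (adjusted p = 0.0329). For LKR13KL MCT4KO against LKR13KL it gave cluster 3 0.38 and cluster 9 0.13, which did not pass.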

Other observations

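Ly6a, an interferon-inducible surface antigen, had a positive log2 fold change between LKR13KL and LKR13K in 7 of 8 classes, a set of values put together after the data were seen. The values were 1.18 ± 0.23 in T cell-like cells, 1.93 ± 0.50 in macrophage-like cells, 2.79 ± 1.00 in cluster 8, 2.38 ± 0.42 in cluster 9, 1.96 ± 0.48 in monocyte-like cells, 2.09 ± 0.75 in neutrophil-like cells, 0.96 ± 0.67 in fibroblast-like cells and −0.08 ± 0.49 in endothelial cell-like cells. Only the value of cluster 9 passed. In cluster 8 Ly6a had 1307 and 57.6 CPM in LKR13KL replicates 1 and 2 and 107 and 89.2 in LKR13K, in neutrophil-like cells 150 and 27.0 against 23.1 and 18.8, and in fibroblast-like cells 1384 and 426 against 686 and 245. Apoe, the lipid transport protein, had −2.54 ± 0.60 in macrophage-like cells, −2.08 ± 0.33 in cluster 8 and −3.29 ± 0.50 in cluster 9, of which the last passed. It had −1.19 ± 0.70 in monocyte-like, −0.78 ± 0.53 in fibroblast-like and −1.88 ± 0.98 in endothelial cell-like cells. In neutrophil-like cells it went the other way, with 0.42 ± 1.03.

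Sprr1a, a cornified envelope gene, differed in fibroblast-like cells from the other classes. In endothelial cell-like cells, and by the medians of the remaining classes, it was lower in LKR13KL and LKR13KL MCT4KO than in LKR13K. In fibroblast-like cells it stood at 24.9 and 7.5 CPM in the LKR13K samples, 32 and 21.2 in LKR13KL and 9.9 and 29.8 in LKR13KL MCT4KO, and in endothelial cell-like cells at 13.1 and 75.4, 1.8 and 5.1, and 0 and 0. Outside these 2 classes its median was 0.122 UMIs per cell over 23 values per class and library in LKR13K, all above 0. In LKR13KL 8 of 21 values were above 0 and in LKR13KL MCT4KO 7 of 18. There Krt8 had medians of 0.177, 0.103 and 0.067 UMIs per cell in the same order, and Krt18 of 0.225, 0.122 and 0.083. Whether these transcripts come from the tumour cells was not tested.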
